A study of Drosophila melanogaster with 2 samples.

How the data were processed

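Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out, per the labels, on whole adult female Drosophila melanogaster of a transgenic line that carries CG14711 fused at its C terminus to enhanced green fluorescent protein, with an antibody against GFP. Chromatin was sheared by sonication to a stated size range of 200 to 800 bp. The series holds 1 group with 2 samples, which the labels number as biological replicates 3 and 4 and draw from separate biosamples. There is no second condition, so the comparisons are between the replicates, between groups of genes, and between peaks and random positions, flanking windows or sites outside the IDR list.

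The 4 peak lists used were all in narrowPeak format with coordinates of the dm6 assembly, per the labels. The deposited text records state that a list was called on the alignment of each replicate with a control alignment, that another list was called on both replicates pooled, and that an optimal list was derived from the others by the irreproducible discovery rate (IDR), a measure of how well ranked peaks repeat between replicates. The control itself was not analysed here. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The signal value of each peak is the authors' own, as the deposited lists give it. Its scale differs between lists (the highest value was 9217 in the pooled list, 5652 for replicate 4 and 3576 for replicate 3), so it was used only to rank and describe peaks within a list. The deposited −log10 q values stop at a maximum in each list: 7049 of the 30000 pooled peaks, 12038 of the 30000 replicate 4 peaks and 10000 of the 30000 replicate 3 peaks share it, and so do all 5654 IDR peaks, at 4.15. The IDR list was tested against the pooled list and holds exactly its 5654 peaks of highest signal. The 3 other lists have 30000 peaks each. Since these lists have the same length, their numbers of peaks say nothing about how much was bound in each replicate. Peak width carries little information in the lists of 30000 peaks: 79.9% of pooled peaks and 82.0% of replicate 4 peaks are 400 bp wide, and 89.9% of replicate 3 peaks are 376 bp wide. In the IDR list 16.3% of peaks are 400 bp wide, and widths run from 100 to 2108 bp (median 307). No row is identical between the replicate lists. The files used hold no read counts, so the depth of either replicate is unknown and intervals given here cover only the sampling of peaks or genes, not the sampling of reads.

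Genes and transcription start sites (TSSs) came from the Ensembl annotation of assembly BDGP6.54, which has the same sequence and coordinates as dm6, and sequence came from the RefSeq copy of that assembly. Annotated transposable elements were left out of the gene set. On arms 2L, 2R, 3L, 3R, 4 and X this left 18164 genes, 13945 of them protein-coding, and 23998 TSS positions. Gene symbols of the fixed lists were matched through the annotation and RefSeq synonyms, and 6 symbols that did not match were not used here.

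A promoter peak is a peak whose summit lies within 500 bp of a TSS, and a gene has a promoter peak when any of its TSSs does. The share of promoter peaks was compared with 1000 random placements of the summits on the same arms (one-sided, smallest possible p 0.001) and, by Fisher's exact test (two-sided), with the 24346 pooled peaks outside the IDR list. Agreement of the replicates was the share of the 5654 best peaks of one list that overlapped, by at least 1 bp, one of the 5654 best of the other, against 1000 random placements. Peaks per arm were compared with arm length by exact binomial tests. For 32 gene lists fixed before the data were examined, the share of members with a promoter peak was compared with all other protein-coding genes by Fisher's exact test (two-sided). Lists that take in a whole RNA class, or fewer than 5 matched genes, were described without a test. For 15 consensus sequences, also fixed in advance, the share of peaks with a match within 50 bp of the summit was compared with 2 controls. The first was windows of the same size centred 300 bp to either side. The second, for promoter peaks, was positions at the same offset from TSSs that had no IDR summit within 1 kb. Such TSSs are called promoters without a peak, but pooled peaks outside the IDR list were not excluded from them. Words of 8 bases were ranked on summits of 2L and 2R and the 10 best were tested on 3L, 3R and X. Median signals were compared by a permutation test with 100000 resamples (two-sided, smallest possible p 1e-05). Benjamini-Hochberg adjustment was applied within each family of tests. Shares carry Wilson 95% confidence intervals. Peaks are not independent samples: all p-values treat peaks or genes of these 2 samples as the units and do not measure variation between further preparations.

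Named genes follow a rule fixed before the data were examined: the 25 promoter peaks of highest signal, by the gene of the nearest TSS and a second gene in opposite orientation within 500 bp, the 5 strongest peaks with no TSS within 500 bp, up to 4 members with the strongest promoter peaks for each list that passed its test, and CG14711. Names given outside this rule are said to have been chosen after their values were seen. Alternatives were other windows (250 and 1000 bp, and 100 bp around summits), protein-coding TSSs alone, peak midpoints, the 2827 IDR peaks of highest signal, other numbers and rankings of best peaks, summit distance instead of overlap, another gene background, other control windows, exchanged discovery and test arms, words of 7 bases, and each replicate's list alone in place of the IDR list.

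The calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Each statistic was tested on simulated data first. With 5654 simulated summits, of which a share was planted at promoters, the promoter share came out at 48.3% where planted and random hits together were expected to give 48.1%. Of 100 simulated gene lists with no difference 4% had an unadjusted p under 0.05, and of 100 lists with 4-fold odds 97% did. The lists with no difference were drawn at random from all protein-coding genes. They therefore could not show false calls from gene spacing or shared promoter peaks. A planted word came out at rank 1 among 10 words, with 0 false calls among the unrelated ones. Simulated peak and control windows were drawn alike from random positions, whereas real ones differ in GC content (34.5% and 43.0%). The simulation therefore could not show false calls from base composition.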

Results

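Peaks of CG14711-eGFP binding were compared in whole adult female flies, in 2 biological replicates (replicates 3 and 4) of a single group. CG14711 encodes a zinc finger protein of the ZAD family, a large insect class of DNA-binding proteins with an amino-terminal zinc-finger-associated domain. The final list held 5654 peaks that passed the irreproducible discovery rate (IDR), drawn from 30000 peaks called on the pooled replicates. Signal values are the authors' and rank peaks within a list. The depth of the libraries is unknown, since the lists carry no read counts. Coordinates are those of dm6.

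The first question was what the tagged protein's own gene showed, since a transgene can add copies of that sequence. The peak at CG14711 (FBgn0037922, 3R, 11623339 to 11624948, plus strand) was the second strongest of the IDR list, with a signal of 6809. It spanned 11622875 to 11623590 on 3R, and its summit at 11623208 lay 131 bp from the CG14711 TSS. The same summit lay 111 bp from a TSS of Zaf1 (FBgn0037921, 3R, 11621466 to 11625644, minus strand), a second ZAD zinc finger gene that runs in the opposite direction and whose span contains CG14711. The peak also had rank 2 in the replicate 3 list (signal 2987) and rank 2 in the replicate 4 list (signal 3835). Further along the same cluster, the promoter of CG14712 had a peak of signal 3215 at 11628391 to 11628843, at rank 46 of the IDR list, rank 57 in replicate 3 and rank 48 in replicate 4. The promoters shared by CG14710 and Jupiter and by CG6813 and CG18764 had IDR peaks of signal 416 and 443. CG14712 and these 4 neighbours were named after their values were seen. No pooled peak lay in the CG14711 gene body more than 500 bp from its TSS (0 peaks).

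**Figure D1:**
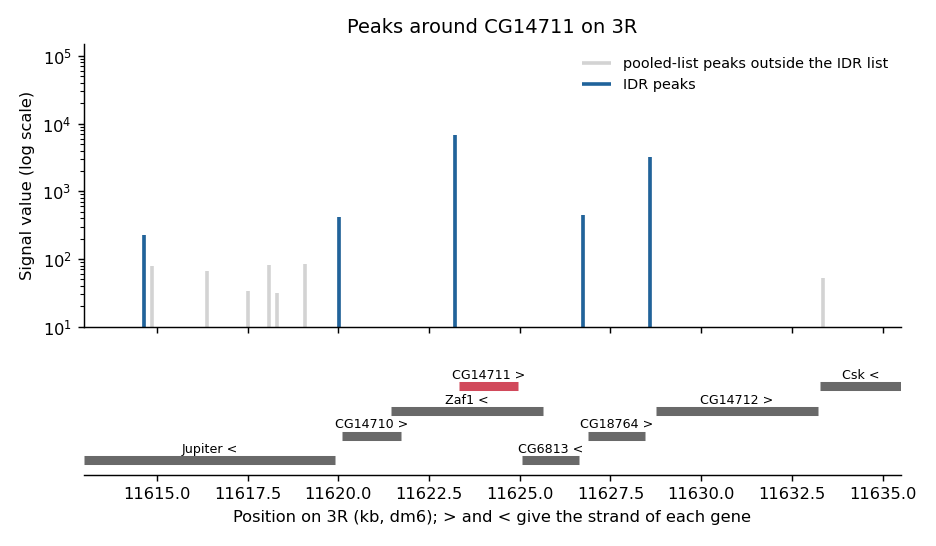
Peaks of the pooled list around CG14711 on 3R. Vertical lines mark summits with their signal value on a log scale (blue, IDR peaks; grey, other pooled peaks), and bars below mark annotated genes with their strand. The 2 tall lines are the shared promoter of CG14711 and Zaf1 (signal 6809) and the promoter of CG14712 (signal 3215).

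The replicates shared most of their strongest peaks. Of the 5654 best peaks of replicate 3, 71.5% (4041 peaks, 95% interval 70.3 to 72.6%) overlapped one of the 5654 best of replicate 4, and 72.1% of the replicate 4 peaks overlapped one of replicate 3. Random placement gave 2.53% ± 0.212 (SD, 1000 placements) and never more than 3.29% (permutation p = 0.001, the smallest 1000 placements can give). Among the numbers of best peaks tried, agreement for replicate 3 was highest at 85.4% of the 500 best. It was 81% of the 100 best and 83.2% of the 250 best. Of the IDR peaks, 80.8% (79.7 to 81.8%) overlapped the best 5654 of replicate 3 and 88.4% (87.5 to 89.2%) those of replicate 4, 70.8% were in both, and 91 peaks (1.61%) were in neither. The best peaks of replicate 4 alone held 996 of the IDR peaks and those of replicate 3 alone held 565. Across the 5224 IDR peaks with a summit within 100 bp in both replicate lists, ranks in the 2 lists had a Spearman correlation of 0.682, a value across peaks, which are not independent replicates.

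**Figure D2:**
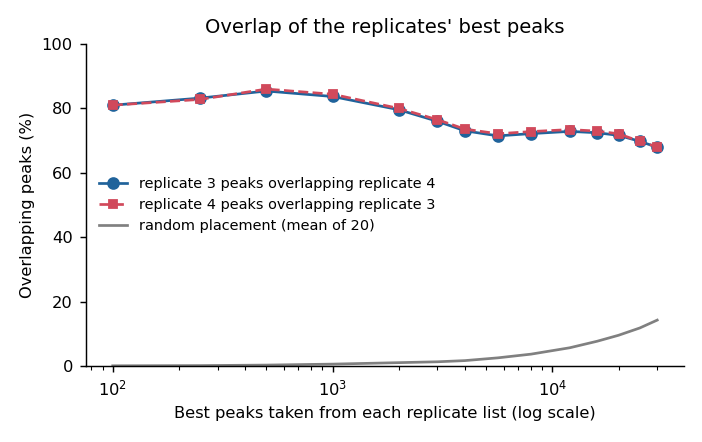
Share of the best peaks of one replicate that overlap the best peaks of the other (vertical axis, percent), by the number of best peaks taken from each list (horizontal axis, log scale). Circles are replicate 3 peaks, squares replicate 4 peaks and the grey line the mean of 20 random placements. The share of replicate 3 peaks was 81% for the 100 best, 85.4% for the 500 best, 71.5% for the 5654 best and 67.9% for all 30000.

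Most strong peaks lay at gene promoters. The summit was within 500 bp of an annotated TSS for 3619 of the 5654 IDR peaks, 64.0% (62.7 to 65.2%). Random positions on the same arms gave 13.6% ± 0.448 (SD), so the share was 4.72 times that of chance (permutation p = 0.001, the smallest possible). Among the 24346 pooled peaks that did not enter the IDR list the share was 32.6%, an odds ratio of 3.67 (Fisher's exact test, p too small to be held as a number). The replicates gave 64.2% and 64.7% when the 5654 best peaks of replicate 4 or of replicate 3 were used alone. Among promoter peaks 77.3% had the summit upstream of the nearest TSS, at a median of -84 bp. Outside promoters, 28.0% of IDR summits were intronic and 5.73% intergenic, while coding exons held 9 summits (0.159%, against 13.8% of random positions). The share at promoters was 73.9% among the 1130 strongest IDR peaks by signal and 58.7% among the 1131 weakest. Promoter peaks had a median signal of 267.7 (interquartile range 188.9 to 513.7, n = 3619) and the others 238.8 (178.3 to 389.1, n = 2035), a ratio of 1.12 (permutation p = 1e-05, the smallest possible).

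**Figure D3:**
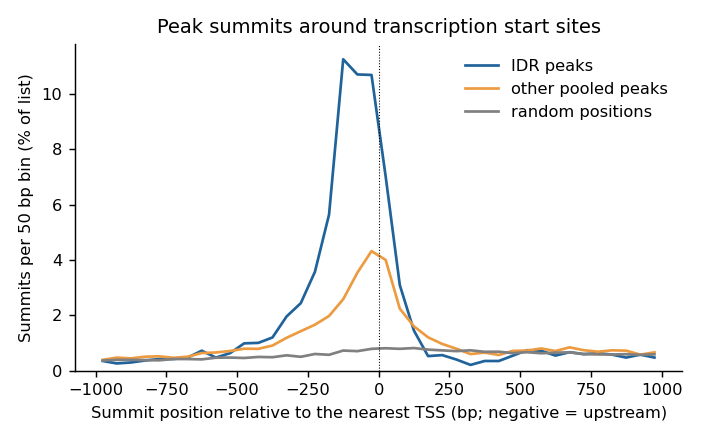
Position of peak summits relative to the nearest TSS (horizontal axis, bp, negative values upstream) as the percent of each list per 50 bp bin. Blue, the 5654 IDR peaks; orange, the other pooled peaks; grey, random positions on the same arms. The IDR peaks reach 11.2% per bin between 150 and 100 bp upstream of the TSS, where random positions stay at 0.73%.

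The strongest promoter peaks belonged to genes of varied function. After CG14711 and Zaf1 came the promoter of sti, the citron kinase of cytokinesis, and tral, a ribonucleoprotein component, with a signal of 5656 at 12514624 to 12515189 on 3L and ranks 5 and 3 in replicates 3 and 4. CG6770, with lncRNA:CR44589 in the opposite orientation, followed (signal 5317, 2L), then l(3)L1231 (5171, 3R), Ugalt (5148, X), a UDP-galactose transporter, and CG14100 (4972, 3L). Gapdh2, a glycolytic enzyme, had 4959 at 15867761 to 15868242 on X. The chromatin genes ph-d, a Polycomb group protein (4920, X), and Hmt4-20, a histone H4 methyltransferase (4792, X), were in the same range, as were lncRNA:CR31044 (4938) and mRpL41, a mitochondrial ribosomal protein (4913, 2R). The rest of the 25 strongest promoter peaks were at CG15012 with Fdx2, a mitochondrial ferredoxin (4705), Phf5a, a splicing factor, with CG31638 (4701), Rad60 with EloA (4531), CG1907 (4429), cg with mRpS16 (4239), CG17982 (4163), sbb (4085), CG13901 with CG13887 (4074), lncRNA:CR43130 with aqz (4051), gro, the Groucho co-repressor (4015), CG7523 with the checkpoint kinase gene Mps1 (3915), Dp1 with the immune adaptor gene imd (3911), Rox8, an RNA-binding protein, with CG5986 (3896), and CG9117 with CG31643 (3859). Of these 25 peaks, 13 had a second gene starting in the opposite orientation within 500 bp. Their summits were 19 to 203 bp from the nearest TSS, and every one was among the 37 best peaks of replicate 3 and the 43 best of replicate 4.

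The strongest peak of all was not at a promoter. It lay in an intron of Tlk, the Tousled-like kinase gene, at 3741906 to 3742816 on X, 2319 bp from the nearest TSS, with a signal of 9217 and rank 1 in both replicates. The next 4 peaks away from promoters were an intergenic peak at 12011767 to 12012668 on 2L (signal 4552), and peaks in introns of CG11050 (2L, 6612341 to 6613024, 4321), CG32772 (X, 4909884 to 4910742, 3651) and ush, a GATA factor partner (2L, 480829 to 481322, 3281).

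Peaks were not spread evenly over the chromosome arms. X held 1173 IDR summits, 49.97 per Mb and 1.18 times the number its length predicts (exact binomial test, adjusted p = 4.49e-09). Chromosome 4 held 31, 23.3 per Mb and 0.55 times its expectation (adjusted exact p = 0.00109). The 4 large autosome arms had 40.5 to 41.1 per Mb, with ratios of 0.957 to 0.971 and none past the threshold. With the number of TSSs as the expectation, the X ratio was 1.26 (adjusted exact p = 2.62e-16) and the deficit on 4 was no longer past the threshold (0.711, adjusted p = 0.0682), whereas 2L (0.876) and 2R (0.874) then were. In comparisons chosen after seeing the data, the X ratio was 1.44 for peaks away from promoters (adjusted exact p = 1.31e-17) and 1.104 for promoter peaks with TSSs as the expectation (adjusted exact p = 0.0187). X had 21.9 peaks away from promoters per Mb against 13.9 on the large autosome arms, 1.58 times as many, and the share of promoter peaks was 56.1% on X and 66.1% on those arms (Fisher's exact test, p = 3.7e-10).

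Gene groups differed widely in how many members had a promoter peak. Of 13945 protein-coding genes, 4276 (30.7%) had one. Of 28 fixed lists that could be tested, 10 had more genes with a promoter peak than other protein-coding genes, 8 had fewer and 10 did not pass the test. Cytoplasmic ribosomal proteins stood highest, at 79 of 93 genes (84.9%, 95% interval 76.3 to 90.8%; odds ratio 12.98, Fisher's exact test, adjusted p = 4.82e-26), among them RpL13 (signal 3119), RpS25 (2077), RpS27 (1950) and RpS14a (1586). Mitochondrial ribosomal proteins had 43 of 73 (58.9%, adjusted exact p = 3.56e-06), led by mRpL41, mRpS16 (4239), mRpS10 (3271) and mRpS23 (2618). Oxidative phosphorylation subunits had 41 of 86 (47.7%, adjusted exact p = 0.00238), with ND-B22 (1983), ND-MNLL (1711), ND-30 (1303) and ND-42 (1267) strongest. Aminoacyl-tRNA synthetases had 13 of 18 (72.2%, adjusted exact p = 0.000997), among them TrpRS (2770), SerRS (1061), ValRS (1021) and ThrRS (725). Proteasome subunits had 24 of 48 (adjusted exact p = 0.0137), with Rpn10 (3808), Rpt3 (1038), Rpn5 (853) and Rpn3 (628). They did not pass with the replicate 3 list in place of the IDR list (20 of 48, 41.7%, adjusted exact p = 0.117) or within 1000 bp of a TSS (adjusted p = 0.0551).

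Of the other lists with more, chromatin regulators had 19 of 29 genes with a promoter peak (65.5%, adjusted exact p = 0.000549), led by ph-d, ph-p (2812), the remodelling ATPase gene brm (2673) and ash2 (2521, the trithorax group). DNA damage response genes had 14 of 20 (70.0%, adjusted exact p = 0.000997), with Irbp (1215), mei-41 (675), Brca2 (284) and spn-B (267), but 9 of 20 with the replicate 3 list in place of the IDR list, which did not pass (45.0%, adjusted p = 0.180). RNA polymerase and general transcription factors had 27 of 55 (49.1%, adjusted exact p = 0.0104), with Taf2 (1919), Taf5 (1363), TfIIB (1170) and Polr2B (1128). Insulator and architectural protein genes had 9 of 15 (60.0%, adjusted exact p = 0.0344), among them Chro (2115), Cp190 (1746), M1BP (661) and Trl (439). They did not pass with the replicate 4 list alone (8 of 15, adjusted exact p = 0.122) or within 1000 bp of a TSS (adjusted p = 0.0776). ZAD zinc finger genes, the family of CG14711 itself, had 18 of 35 (51.4%, adjusted exact p = 0.0176). This list did not pass within 1000 bp (adjusted exact p = 0.0742) or against genes with a pooled peak (adjusted exact p = 0.481). With genes that have another gene's TSS within 1000 bp left out, the share was 15.4%, close to the 16.6% of other genes (odds ratio 0.916). That share rests on 2 of 13 genes and did not pass its test, in an alternative chosen after seeing the data. CG14711 and Zaf1 count as 2 members with 1 shared peak. The strongest peaks of the list were the shared peak of Zaf1 and CG14711, that of CG4820 (2077), which it shares with RpS25, and that of Meics (965).

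Among the 8 lists with fewer, chemoreceptor genes had 2 of 179 (1.12%, odds ratio 0.0251, adjusted exact p = 1.86e-24), at Gr63a (signal 246) and Ir60e (196). No promoter peak was found for odorant binding proteins (0 of 51, adjusted exact p = 8.64e-08), testis and seminal fluid genes (0 of 30, adjusted p = 0.000127), gut digestive enzymes (0 of 23, adjusted p = 0.000997) or antimicrobial peptides (0 of 15, adjusted p = 0.0158). Muscle structure genes had 2 of 23 (8.70%, adjusted exact p = 0.0344, and 0.0597 with the replicate 3 list alone), at sls (351) and Tm1 (167), and cytochrome P450 genes had 14 of 85 (16.5%, adjusted p = 0.01), with Cyp6u1 (1062), Cyp6t1 (399), Cyp4d20 (354) and Cyp9f2 (349) strongest. Replication-dependent histone genes had 0 of 111 (adjusted exact p = 3.07e-17), but they are near-identical tandem copies, where short reads cannot be assigned to a single gene. Ovarian and germline groups did not pass the test in the main setting: 12 of 27 oogenesis and maternal patterning genes (44.4%, adjusted exact p = 0.174), 6 of 27 piRNA pathway genes (22.2%, adjusted p = 0.424) and 3 of 20 eggshell and yolk genes (15.0%, adjusted p = 0.176). Eggshell and yolk genes had fewer, past the threshold, within 250 bp (0 of 20, adjusted exact p = 0.00696) and against genes with a pooled peak (3 of 17, adjusted p = 0.0255). Within 1000 bp they were near other genes (6 of 20, 30.0% against 34.2%, adjusted exact p = 0.870). Also not past the threshold in the main setting were cell cycle genes (16 of 35, adjusted exact p = 0.0916, but more, at 19 of 35 and 0.00971, with the replicate 4 list alone), translation initiation factors (20 of 44, adjusted p = 0.0703, but more, at 0.00983, within 250 bp and, at 0.0147, with the replicate 4 list alone), fat body (7 of 16, adjusted p = 0.303), heat shock proteins (8 of 26, adjusted p = 1), neuronal (4 of 24, adjusted p = 0.205), photoreceptor (2 of 17, adjusted p = 0.148) and Hox genes (0 of 8, adjusted p = 0.148). With the replicate 3 list alone neither cell cycle genes (15 of 35, adjusted exact p = 0.132) nor translation initiation factors (15 of 44, adjusted p = 0.547) passed. Among lists described without a test, 24 of 290 tRNA genes, 14 of 269 small nucleolar RNA genes, 3 of 32 spliceosomal snRNA genes and 0 of 2 roX genes had a promoter peak. The first 2 of these counts depend on the window. Within 250 bp they were 15 tRNA and 7 small nucleolar RNA genes, and within 1000 bp 37 and 65.

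Background and gene spacing bear on these lists. Against only those genes with a pooled peak at a promoter, 2 lists kept more genes with a peak, cytoplasmic and mitochondrial ribosomal proteins, and 6 had fewer (cytochrome P450, chemoreceptors, odorant binding proteins, gut digestion, muscle structure, and eggshell and yolk). With the 2827 strongest IDR peaks 5 lists had more (both ribosomal lists, aminoacyl-tRNA synthetases, chromatin regulators and ZAD genes) and 5 had fewer, while gut digestion (adjusted exact p = 0.0615), antimicrobial peptides (adjusted p = 0.167) and muscle structure (adjusted p = 0.183) no longer passed. Their shares stayed low, at 0 of 23, 0 of 15 and 1 of 23 genes, while the share of other genes fell to 17.9%. The replicate 4 list alone gave 11 lists with more and 8 with fewer, and the replicate 3 list alone 8 and 7. With genes that have another gene's TSS within 1000 bp left out, an alternative chosen after seeing the data, 2 lists had more and 1 had fewer (chemoreceptors). Those with more were cytoplasmic ribosomal proteins, at 76.2% against 16.4% of other genes, and chromatin regulators, at 60.0% against 16.5%. Odorant binding (0 of 25), histone (0 of 23), testis and seminal fluid (0 of 19), gut digestion (0 of 14) and antimicrobial peptide genes (0 of 7) still had no peak. These smaller lists no longer passed, nor did muscle structure (1 of 18) or cytochrome P450 (9 of 65, 13.8% against 16.6%). Mitochondrial ribosomal proteins then had 3 of 13 (23.1%, against 16.5% of other genes, odds ratio 1.51, adjusted exact p = 0.68), and no aminoacyl-tRNA synthetase gene was left (0 genes). DNA damage response genes and insulator and architectural protein genes each had a peak at 0 of 3, too few for a test. Of the 48 members with the strongest peaks in the lists that passed, 21 had a summit nearer to another gene's TSS. Among them were RpL13 (nearest Dref), mRpS10 (Art3), mRpS23 (CenG1A), TrpRS (Vps16A), Irbp (mgr), mei-41 (TH1) and Brca2 (CG4612). These other genes were named after their values were seen.

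**Figure D4:**
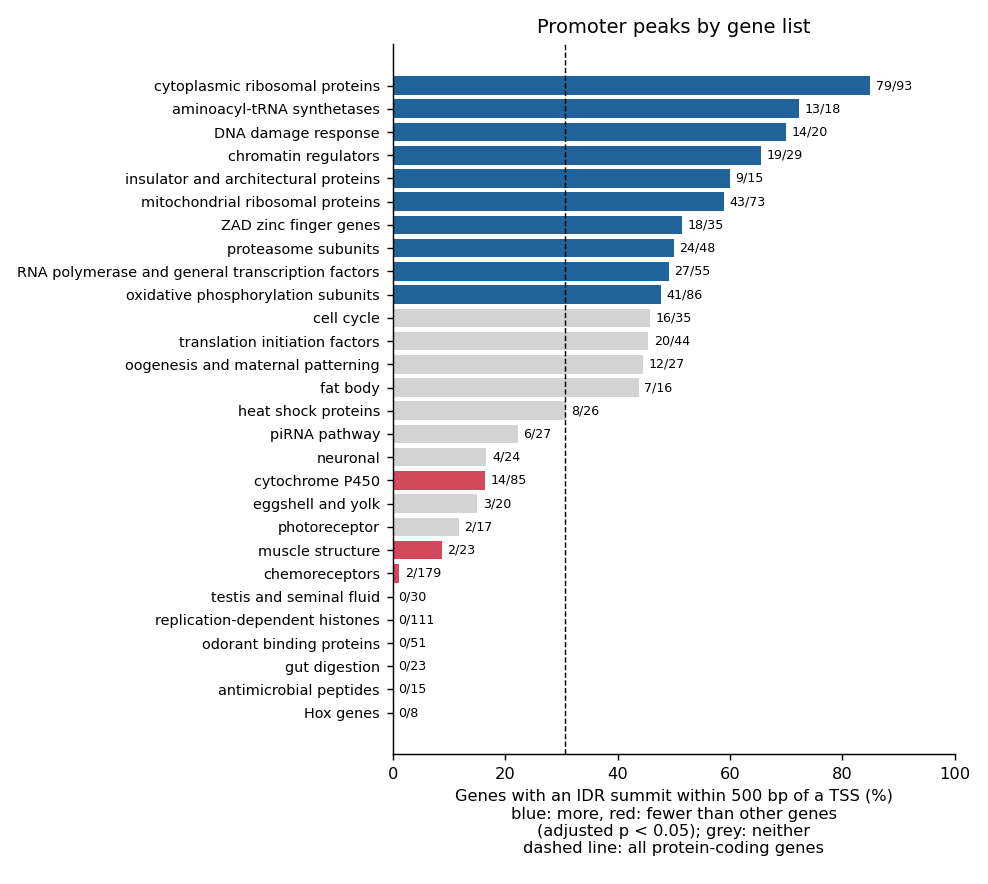
Percent of genes in each of the 28 tested lists with an IDR summit within 500 bp of a TSS (horizontal bars), with the count of genes beside each bar. Blue lists had more and red lists fewer than other protein-coding genes at an adjusted p under 0.05, grey lists neither, and the dashed line is the 30.7% of all protein-coding genes. Cytoplasmic ribosomal proteins reach 84.9% and chemoreceptors 1.12%.

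Sequence at the summits was AT-rich and held a recurring word. The 100 bp around IDR summits had a GC content of 34.5%, against 43.0% in windows 300 bp away. The best 8-base word on 2L and 2R was CAACCCTG. On 3L, 3R and X it lay within 50 bp of 101 of 3635 summits (2.78%) and in 18 of 7270 control windows (0.248%), 11.2 times as often (Fisher's exact test, adjusted p = 2.03e-30). The overlapping word AGGGTTGC (2.81% against 0.303%, adjusted exact p = 1.05e-28) and the related CAACACTG (2.53% against 0.399%, adjusted p = 2.13e-21) were also among the 10 words, as were ATCGATAG (2.59% against 0.509%, adjusted p = 3.2e-19) and 6 words of A and T alone, at 2.02 to 3.17 times their control frequency. All 10 passed on the test arms. The control windows were not matched for GC content, so the excess of the 6 words of A and T cannot be told apart from AT-rich summits. At promoters without an IDR peak, taken at the same distance from the TSS, CAACCCTG was found once in 2252 windows, against 62 of 2252 promoter summits on the same arms (adjusted exact p = 9.19e-17). Of the 25 strongest promoter peaks, 4 had CAACNCTG within 50 bp of the summit, at CG15012, cg, lncRNA:CR43130 and Dp1.

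**Figure D5:**
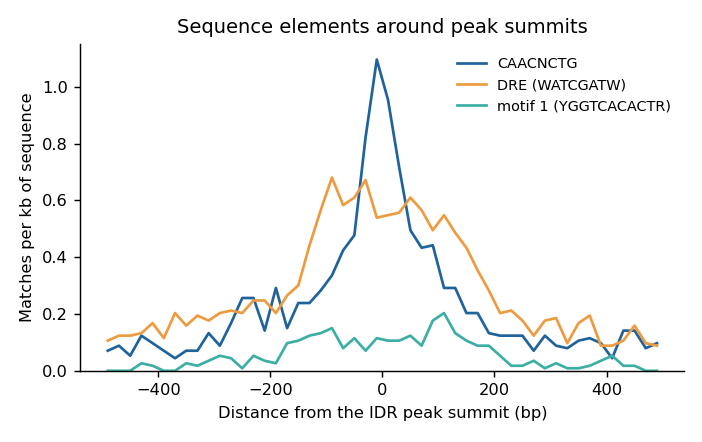
Matches of CAACNCTG (blue), the DNA replication-related element (orange) and motif 1 (green) per kb of sequence, by distance from the summit of the 5654 IDR peaks in bins of 20 bp. CAACNCTG rises to 1.097 per kb at the summit from 0.0707 per kb in the outermost bin upstream. The other sequences are not highest at the summit. The DNA replication-related element has 0.539 per kb in the bin from -20 bp and 0.681 in the bin from -100 bp. Motif 1 has 0.115 per kb in the bin from -20 bp and 0.203 in the bin from 100 bp.

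Of 15 fixed consensus sequences, 8 were more frequent at summits than in flanking windows, 4 were less frequent and 3 did not pass the test. The DNA replication-related element, bound by DREF at housekeeping promoters, was in 5.01% of peaks and 1.56% of control windows (odds ratio 3.33, Fisher's exact test, adjusted p = 3.42e-35). The BEAF-32 core was in 19.2% against 12.4% (adjusted exact p = 6.41e-31), the TATA box sequence in 21.5% against 11.3% (adjusted p = 2.83e-65), Ohler 7 in 3.24% against 1.11% (adjusted p = 2.6e-20), the Ohler 5 E-box in 2.92% against 1.49% (adjusted p = 2.18e-09), motif 1 in 0.990% against 0.265% (adjusted p = 5.12e-09), Ohler 6 in 0.601% against 0.0796% (adjusted p = 2.39e-09) and the Su(Hw) core in 0.336% against 0.159% (adjusted p = 0.0319). The GAGA element of Trl (1.64% against 2.95%, adjusted exact p = 2.46e-07), the downstream promoter element (1.34% against 2.10%, adjusted p = 0.000738), the longer GA repeat of CLAMP (0.371% against 0.646%, adjusted p = 0.0345) and the TCT initiator of ribosomal protein genes (10.2% against 11.5%, adjusted p = 0.0152) were less frequent. Windows lay around summits, at a median of -84 bp from the TSS for promoter peaks, not at core promoter positions. The downstream promoter element, TCT and initiator counts are therefore of sequence matches, not of elements in place. CTCF, Zelda and initiator sequences did not pass (adjusted exact p = 0.362, 0.342 and 0.866). Neither set of control windows was matched for GC content. GC content was 34.5% at summits and 43.0% in flanks, and 35.2% at promoter peaks and 40.6% at promoters without a peak. Differences in the TATA box, GAGA, CLAMP and downstream promoter element sequences therefore cannot be told apart from base composition. The Su(Hw) core, Ohler 6 and the DNA replication-related element are also rich in A and T. Base composition may account for part of their excess, which was not tested. Against promoters without a peak at the same TSS offset, the TCT initiator was instead more frequent (10.1% against 8.12%, adjusted exact p = 0.00619), the CTCF core was more frequent (2.74% against 1.85%, adjusted p = 0.02), the initiator (9.48% against 13.7%, adjusted p = 6.82e-08) and the Zelda site (odds ratio 0.287, adjusted p = 0.000253) were less frequent, and Ohler 6, GAGA, Su(Hw) and the downstream promoter element no longer passed. In that comparison the DNA replication-related element (7.10% against 3.79%, odds ratio 1.94) and the TATA box sequence (21.0% against 16.9%, odds ratio 1.31) still passed, with smaller odds ratios. With the replicate 3 list in place of the IDR list none of the 4 less frequent sequences passed (adjusted exact p = 0.916 for GAGA and for CLAMP, 0.132 for the downstream promoter element and 0.713 for TCT), while the Zelda site was less frequent (adjusted p = 0.0257). Su(Hw) did not pass within 100 bp (adjusted exact p = 0.093) or with the replicate 4 list alone (adjusted p = 0.218), and TCT and CLAMP did not within 100 bp (adjusted p = 0.093 for each), nor TCT with the 2827 strongest peaks (adjusted p = 0.303).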

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

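Of the tests in this part, those of the summit word at the CG14711 locus and of the signal at ribosomal protein promoters were set before their results were seen. The X ratio with TSSs as the expectation was fixed before the data were examined, but its bounds were set after it was seen. The other tests were chosen after the result was seen. The design names no second group, so biological explanations were tested only through sequence and gene lists.

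A signal lay in data that the comparisons of the report use only as background. In the pooled list, 1395 peaks had the highest −log10 q that the list gives, as did all IDR peaks, but were outside the IDR list. Their signal was at most 146.3, just below that of the weakest IDR peak.

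The pair of strong peaks at the CG14711 locus is the first pattern a reader would want to follow up, since the line carries a tagged copy of the gene. Extra copies of CG14711 alone are argued against for the CG14712 peak, whose summit lies 3640 bp beyond the end of CG14711. Extra copies of the whole neighbourhood stay open for both peaks: the other 20 pooled peaks within 20 kb had a median signal of 61.2, at the 26th percentile of the same measure around the 100 other strongest peaks (median 75.7, interquartile range 60.9 to 103.5), inside that spread. The bound first set would have counted this percentile against the explanation; it was changed after the value was seen, because raised copies might also bring weak peaks over the cut of the list, which holds a median down. At its own peak, extra copies of CG14711 alone cannot be told apart from binding: 0 pooled peaks lay in the gene body, but a caller that subtracts an even background might leave an amplified gene without peaks, and the extent of the insert is not given in the sources used here. Binding at an exact copy of the common word at the summit is argued against, since 0 of the 2 summits had CAACNCTG within 50 bp. Variants of the word and copies farther from these summits were not examined. The word was present at 7.55% of all IDR summits, so its absence does not set these 2 peaks apart. Binding of the protein, or of a partner, at its own promoter through other sequence remains an untested hypothesis.

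Promoter peaks at lists such as the ribosomal proteins, with few at lists such as the chemoreceptors, form a pattern that active, open promoters might also give without specific binding. Peaks at cytoplasmic ribosomal protein promoters, among the most transcribed genes, had a median signal of 345.5 against 265.5 for other promoter peaks (permutation p = 0.0116, 79 peaks), at a median percentile of 62.3, so an effect of transcription level stays open. Signal with no relation to sequence is argued against for part of the strongest peaks. CAACNCTG was within 50 bp of 14.4% of the 1130 strongest summits and 5.31% of the 1131 weakest. The ratio was 2.72 (Fisher's exact test, p = 1.67e-13). Below the strongest 1130 the share changed little, at 6.37%, 6.10%, 5.57% and 5.31% in successive groups of 1131. Promoter peaks made up 73.9% of the strongest group and 58.7% of the weakest. They held CAACNCTG more often than other peaks (8.87% against 5.21%), so peak position may contribute to the ratio, which was not tested. Nor does the ratio separate specific binding from open promoters that hold the element. CAACNCTG was present at 7.55% of all IDR summits, so the Fisher test says nothing about the remaining peaks. An unspecific immunoprecipitation from untagged flies was not analysed here and would decide more.

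The excess of peaks on X could come from the control, from promoter number or from sequence. A control with fewer X copies, for example from males, would raise signal at promoter and other peaks on X to a similar degree. The X share was 20.7% among IDR peaks and 18.7% among the other pooled peaks, a ratio of 1.11 (Fisher's exact test, p = 0.000549). That contrast decides little alone, because peak numbers fell with signal as a power of 1.22 among IDR peaks and 1.03 among the others. An even raise could then also give a slightly higher X share among IDR peaks. X had 28.03 promoter peaks per Mb against 27.0 on the large autosome arms, but 21.9 other peaks per Mb against 13.9. These densities argue against such a control as the whole cause. A smaller contribution stays open, since promoter peaks on X still exceeded the number that TSSs predict (ratio 1.104). Promoter number is argued against, since the ratio was 1.26 with TSSs as the expectation. CAACNCTG was 1.15 times as frequent per Mb on X as on the large autosome arms, which met the test of this explanation as first set, on frequency alone. That test was replaced after its result was seen: IDR peaks without it kept an X ratio of 1.19 (exact binomial test, p = 2.17e-10), which argues against its density as the whole cause, while a smaller contribution stays open.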

How the results depend on the processing

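The alternatives that restrict peaks to those with CAACNCTG, leave out crowded genes, free the fifth base of the word or split peaks by TSS distance were chosen after seeing the data; all others were fixed before the data were examined. The alternative without crowded genes replaced an earlier one, leaving out genes that share a promoter peak, which was run and dropped because it selects genes on having a peak. The overlap of the replicates stayed far above chance, at 76.4% with 2827 peaks, 72.8% with 11308, 65.5% ranked by q and 64.2% by summit distance. Promoter share lay between 54.5% and 74.5% and passed in every setting run. The ratio of promoter to distal signal lay between 1.09 and 1.13. Ranking signal by q gave no value there, because all IDR peaks hold the same q, and the q ranking of replicate lists has long ties. Recovery of IDR peaks rose to 99.2% (replicate 3) and 99.8% (replicate 4) in the full lists and to 97.5% and 99.8% for the 2827 strongest IDR peaks, and was 76.1% and 85.9% by summit distance; fuller lists and stronger peaks give this by construction. With TSSs as the expectation, 2L (0.876) and 2R (0.874) passed and 4 (0.711) did not. Density on 2R passed with the 2827 strongest (0.901) and for peaks away from promoters (0.816). For promoter peaks against TSSs, 2L passed (0.903) and 4 did not (0.753). The X ratio lay between 1.104 and 1.44 and passed throughout. With each replicate's list alone, the 3L ratio was 0.941 to 0.965 and passed without replicate 3. The cause of these arm changes was not tested. Lists with more promoter peaks numbered 2 against genes with a pooled peak, 5 with the 2827 strongest, 3 for peaks with CAACNCTG and 2 without crowded genes, in place of 10; lists with fewer numbered 6 against genes with a pooled peak, 5 with the 2827 strongest, 0 for peaks with CAACNCTG and 1 without crowded genes, in place of 8. Each of these tests fewer peaks or genes, but against genes with a pooled peak the differences themselves also shrank. Aminoacyl-tRNA synthetases stayed at 13 of 18 genes, while the share of other genes rose from 30.6% to 50.3%. Their odds ratio fell from 5.89 to 2.57, and that of DNA damage response genes from 5.29 to 2.31. Of the 10 lists with more, only proteasome subunits showed no such fall (2.27 and 2.38). Without crowded genes, 15.4% of ZAD genes (2 of 13) had a peak, against 16.6% of other genes. With CAACNCTG alone 2.86% of ZAD genes (1 of 35) and 0 of 20 DNA damage response genes had one, against 3.15% of other genes for each list. These counts are too small to show a difference in either direction, and no cause was tested. Motifs less frequent at summits numbered 1 to 4 with each replicate alone, the 1 being the Zelda site, which did not pass for IDR peaks, and the GAGA share, 1.64% of IDR peaks, was 1.22% without replicate 3 and 2.79% without replicate 4, where it was no longer below its control; the cause was not tested. The TCT initiator (10.1%) turned against promoters without a peak, where the control holds the same distance from the TSS. Among single genes, lists and motifs, the alternatives gave 224 results with an unchanged outcome, 59 weaker, 11 stronger, 5 reversed (the ZAD, DNA damage, GAGA and TCT values above) and 53 moved ranks. An unchanged outcome does not mean the same side, since results that passed in neither setting could change side. Cell cycle genes did so (odds ratio 1.91, and 0.83 against genes with a pooled peak). The reversed ZAD and DNA damage values rest on 2 of 13, 1 of 35 and 0 of 20 genes, and none passed its test. Depth is unknown for both replicates, so differences between their lists cannot be set against it.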

Other observations

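Protein-coding genes were also scanned by the letters that open the gene symbol, for 70 stems with at least 10 genes, a scan chosen after seeing the data. Of these stems, 25 hold members of the fixed lists. Besides the ribosomal proteins, 16 of 21 PIG genes of glycosylphosphatidylinositol anchor synthesis had a promoter peak (76.2%, Fisher's exact test, adjusted p = 0.000157), as did 11 of 15 Usp genes (adjusted p = 0.00411), 12 of 19 Sec genes (adjusted p = 0.0181), 12 of 20 Atg genes of autophagy (adjusted p = 0.0241) and 7 of 10 EMC genes of the endoplasmic reticulum membrane complex (adjusted p = 0.036). No peak was found at 70 Cpr cuticle protein genes (adjusted exact p = 2.03e-10), 25 Osi genes (adjusted p = 0.000824), 19 Acp genes of the male accessory gland (adjusted p = 0.00802; 6 are in a fixed list) or 16 Jon digestive proteases (adjusted p = 0.0184; 7 are in a fixed list). In all, 11 stems had more genes with a peak than other protein-coding genes and 16 had fewer.

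Many promoter peaks had TSSs of both strands nearby. Of 3619 promoter IDR peaks, 1274 (35.2%, 95% interval 33.7 to 36.8%) had protein-coding TSSs of both strands within 500 bp, against 1008 of 7942 promoter peaks of the pooled list outside the IDR list (12.7%, 12.0 to 13.4%; odds ratio 3.74, Fisher's exact test, p = 2.79e-164). This comparison, too, was chosen after seeing the data.

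The word family CAACNCTG was defined after its members were seen on 2L and 2R and then tested on the other arms. On 3L, 3R and X it lay within 50 bp of 7.40% of summits and 1.07% of flanking windows (Fisher's exact test, p = 6.59e-66), and at 8.39% of promoter summits against 1.07% of promoters without a peak (p = 2.35e-34). By the fifth base, C gave 11.2 times the flank frequency, T 7.53, A 6.34 and G 2.67. Peaks with it had a median signal of 351.9 against 252.3 for the rest (427 peaks, permutation adjusted p = 3e-05), whereas peaks with the DNA replication-related element were weaker than the rest (220.8 against 257.5, adjusted p = 0.00829), as were those with motif 1 (195.8 against 257.1, adjusted p = 0.0363). Both CAACNCTG and the DNA replication-related element were present at 41 summits, where 21.4 would be shared if they were independent (Fisher's exact test, p = 3.98e-05). Any of the 3 sequences was present at 12.7% of IDR summits.

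Transposable elements held few summits. Of IDR summits, 12 (0.212%) lay in an annotated element, against 5.87% of random positions, and repeated sequence is hard to map with short reads. X peaks away from promoters were stronger than those on the large autosome arms (median signal 266.1 and 231.5) and 81.9% of them were intronic, against 76.6%; these differences were not tested.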
